A study of Sus scrofa with 16 samples.

How the data were processed

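RNA of the left ventricle was measured in 16 pigs (Yorkshire x Landrace), 8 with a myocardial infarction (MI) and 8 with a sham operation, 3 weeks after surgery. By the labels each group held 4 females and 4 neutered males. The labels state that frozen myocardium was crushed, that total RNA was extracted with Trizol and cleaned on columns, and that biotin-labelled cRNA was prepared by the array maker's standard protocol. Each animal gave 1 Affymetrix porcine array. The labels do not say which part of the left ventricle was taken, nor how far it lay from the infarct.

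The deposited values are log2 signals, as judged from their range of 2.87 to 14.9, the absence of negative values and equal medians. All 16 arrays had the same median (6.24) and the same minimum (2.87), as after a normalization between arrays. The normalization, the summary method and the software of the authors are not given in the sources used here. The values were used as deposited, with no offset and no further scaling. Arrays give no counts, so the number of animals and the signal over background limit the precision.

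The array held 24123 probe sets. The 124 control probe sets were left out of the tests and used as controls, which left 23999 probe sets. Of these, 10069 carried 1 gene symbol, 198 carried several symbols and 13732 carried none. The 10069 stood for 6765 genes, and each gene was represented by its probe set with the highest mean over the 16 arrays. Positions came from the RefSeq annotation of the pig assembly Sscrofa11.1, matched by Entrez identifier (6700 of 6774 identifiers found). No genome sequence was at hand, so probe sequences were not aligned.

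Differences were tested in R 4.3.3 with limma 3.58.1. The fit had 1 coefficient for each of the 4 cells of group and sex, which left 12 residual degrees of freedom, and moderated variances (prior degrees of freedom 3.28). The comparisons were MI against sham (the mean of the difference in females and in males), MI against sham within each sex, the difference between those (the interaction, female minus male), female against male over both groups, and female against male in sham animals. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 23999 probe sets, and an adjusted p under 0.05 was taken as passing. Single measures per animal were compared by exact permutation tests over all splits of the animals into groups of the same size.

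A total of 42 gene lists (28 of processes and 14 of cell types) were written down in advance. The 40 lists with at least 3 measured genes were tested with camera of limma at a preset correlation between genes of 0.01, with adjustment over the lists. Camera with a correlation estimated for each list and the rotation test fry were run beside it. Camera asks whether a list moved more than the other genes. The directional test of fry asks whether the genes of a list moved, on balance, one way, and its mixed test asks whether they changed in either direction; neither compares a list with other genes. For each list the members passing were counted over all probe sets tested and also when adjusted over the list alone.

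Genes to be named were set by a rule: the 12 largest increases and the 12 largest decreases among genes passing in MI against sham, the 4 members of each list with the lowest p, the genes passing in female against male (up to 8 in each direction), the measured members of the sex-linked list, and the 4 genes with the lowest interaction p if none passed. The comparisons, the lists, the naming rule and the first set of alternatives were fixed before the data were examined.

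The alternatives of that first set were: group without sex; the animal number in the labels as a block; quantile normalization; median centring of each array; keeping the 16000 brightest probe sets; an offset of 32 added before the logarithm; an intensity trend with robust estimation; array weights; leaving out each animal in turn; a fold change of at least 1.5; an adjusted p under 0.01; the mean over all probe sets of a gene; and the estimated correlation for lists. Further alternatives were chosen after seeing the data. These concerned 2 sets of arrays that the spike-in controls separated (set A, 11 arrays; set B, 5 arrays), used as a block or alone, the omission of the library labelled MI female 7 together with that block, the probe sets above background, and the 12000 brightest probe sets. Background was the highest single value among 23 control probe sets without target RNA in the sample (4.99), and a probe set counted as above background if its mean in either group exceeded it.

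The fit was tested on simulated data with the same 16 arrays and 23999 probe sets, in which 100 probe sets were changed by 0.5 and 100 by 1 on the log2 scale. For MI against sham it recovered 59 and 98 of them, within females 29 and 86, within males 31 and 83, for the interaction 7 and 60, for female against male 63 and 95, and for female against male in sham 31 and 86. None was given the wrong direction. Unchanged probe sets made up 13 of the 170 that passed for MI against sham, 4 of 119 within females, 8 of 122 within males, 5 of 72 for the interaction, 8 of 166 for female against male and 6 of 123 for the same in sham. A shift of 0.3 put into 1 list was found, and 0 of the other lists passed by camera. The simulated probe sets varied independently of each other and held no sets of arrays. These shares therefore do not cover genes that vary together, which bears most on the list tests.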

Results

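Gene expression was measured on 16 porcine arrays, 1 per animal, from the left ventricle of 8 pigs with a myocardial infarction (MI) and 8 sham-operated pigs (Sham), 3 weeks after surgery. Each group held 4 animals labelled female and 4 neutered animals labelled male. Females and males below are those of the labels, although MI 7, labelled female, carried the male pattern at chromosome Y transcripts. Values are log2 signals as deposited, and animals are named by group and number. The correlation between any 2 arrays lay between 0.972 and 0.992 across probe sets, which are not independent replicates. Control probe sets without target RNA in the sample had single values from 3.08 to 4.99 in these arrays, and 16731 of the 23999 probe sets had a group mean above 4.99 while 7268 did not.

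The arrays fell into 2 sets that the labels do not mention. The poly-A spike-in transcripts, added before labelling, stood 1.88 ± 0.32 (SD, n = 11) below the hybridisation controls in set A and 4.57 ± 0.45 (n = 5) below them in set B, on the log2 scale. These controls define the sets, so their difference is not a test of it. Set B held MI 7, MI 8, Sham 6, Sham 7 and Sham 8. The first principal component, with 26.7% of the variance, averaged 14.1 ± 8.14 in set A and -31.1 ± 3.91 in set B (exact permutation test, two-sided, p = 0.000229, the smallest the 11 and 5 arrays allow). The 3' minus 5' signal of the actin control was 2.64 ± 0.29 in set A and 1.42 ± 0.14 in set B (exact p = 0.000229), and 2.39 ± 0.59 in MI against 2.12 ± 0.68 in sham animals (n = 8 each, exact p = 0.394). The second component, with 13.04% of the variance, averaged 14.3 ± 3.47 in MI and -14.3 ± 7.78 in sham animals (exact p = 0.000155). By the labels set B held 2 MI females (MI 7 is 1 of them), 1 sham female, 2 sham males and 0 MI males, so the comparisons were also run with the set as a block and within set A.

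**Figure D1:**
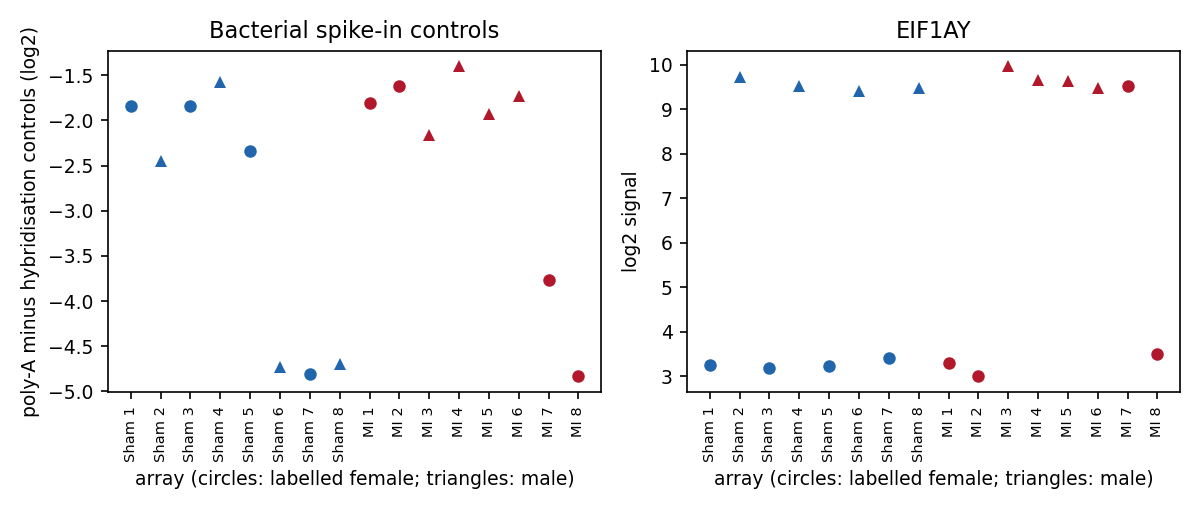
Left, the mean log2 signal of the poly-A spike-in controls minus that of the hybridisation controls for each array; right, the log2 signal of EIF1AY for each array, by group and labelled sex. The 5 arrays of set B lie between -4.83 and -3.77 on the left, and MI 7, labelled female, lies at 9.51 on the right among the arrays labelled male.

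The main question was which transcripts differ in the left ventricle 3 weeks after an infarction. MMP14, the membrane-anchored metalloproteinase that cleaves collagen, rose from 5.86 ± 0.27 in sham to 6.99 ± 0.32 in MI animals (mean ± SD, n = 8 each), a difference of 1.13 (SE 0.14, adjusted p = 0.00014) or 2.19-fold, with all 8 MI animals above all 8 sham animals. MMP9, the gelatinase of neutrophils and macrophages, rose from 4.76 ± 0.16 to 5.29 ± 0.13 (adjusted p = 0.000569). CD14, the lipopolysaccharide co-receptor of monocytes and macrophages, rose by 0.76 (SE 0.14, adjusted p = 0.00314), and PPARG, the nuclear receptor that drives fat cell formation, rose by 0.71 (SE 0.15, adjusted p = 0.0076), with 8 of 8 MI animals above the sham mean for both. MAGOHB, a core protein of the exon junction complex, fell from 7.24 ± 0.20 to 5.67 ± 0.15 (SE of the difference 0.09, adjusted p = 5.19e-07), a 2.97-fold lower signal, with no overlap between the groups. PC, pyruvate carboxylase, which refills the citric acid cycle, fell by 0.57 (SE 0.08, adjusted p = 0.00048), with all 8 MI animals below the sham mean.

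MMP14 (Entrez 397471) lies on chromosome 7 from 76174502 to 76185931, MMP9 (654325) on chromosome 17 from 48179690 to 48186782, and CD14 (100037938) on chromosome 2 from 142348036 to 142349686. PPARG (397671) lies on chromosome 13 from 68301566 to 68433951, MAGOHB (100518306) on chromosome 5 from 61425699 to 61434026, and PC (397630) on chromosome 2 from 5566608 to 5587797. With the spike-in set as a block the differences were 1.18 for MMP14, 0.79 for CD14, 0.72 for PPARG and -1.55 for MAGOHB, and each passed, as they did within set A. There they were 1.16, 0.99, 0.85 and -1.52 (adjusted p from 0.000626 to 0.0258). Within set B, with 5 arrays, they were 1.30, 0.53, 0.35 and -1.69 (adjusted p from 0.0717 to 0.538), none of which passed.

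The other genes among the 12 largest increases were HBM, UBXN2A, LOC100517803, AHSP, MYO5B, SSTR1, IYD, CAMK1D and RAB19, with differences from 0.75 to 1.10. The other genes among the 12 largest decreases were EFHD1, ALG8, FPGT, ZNF232, CALCR, KIF5C, DNAJC24, FGG, LOC396711, CCL3L1 and ZDHHC5, with differences from -0.65 to -1.12. They include genes of varied kinds, such as SSTR1, a somatostatin receptor, CALCR, the calcitonin receptor, ALG8, an enzyme of protein glycosylation, and KIF5C, a kinesin motor. EFHD1, a mitochondrial calcium-binding protein, fell from 8.21 ± 0.36 to 7.09 ± 0.92, with a difference of -1.62 in set A and 0.07 in set B (adjusted p = 0.0162 and 0.949; 0.0151 to 0.949 over 30 alternatives). All 24 passed with the set as a block, and 23 in set A, where MYO5B had an adjusted p of 0.0628 (0.00276 to 0.42 over 30 alternatives); in set B alone 0 passed by limma and 1, EFHD1, had the other sign. Of the 24, 23 were above background, FGG being the exception, and the 8 other probe sets of these genes gave 0 passing differences in either direction. Being above background required only 1 group mean over 4.99, and SSTR1 in sham animals ran from 4.12 to 4.47. Only 15 of the 24 were among the 16000 brightest probe sets, and 13 of these passed when those were tested alone. The top genes were therefore not all clear of the dim range. EFHD1 did not pass without any 1 of MI 1, 2, 4, 5 or 6 or Sham 3 to 7 (adjusted p up to 0.0755), nor AHSP without any 1 of MI 1, 2, 4, 5 or 7 or Sham 2 to 7 (up to 0.0727).

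**Figure D2:**
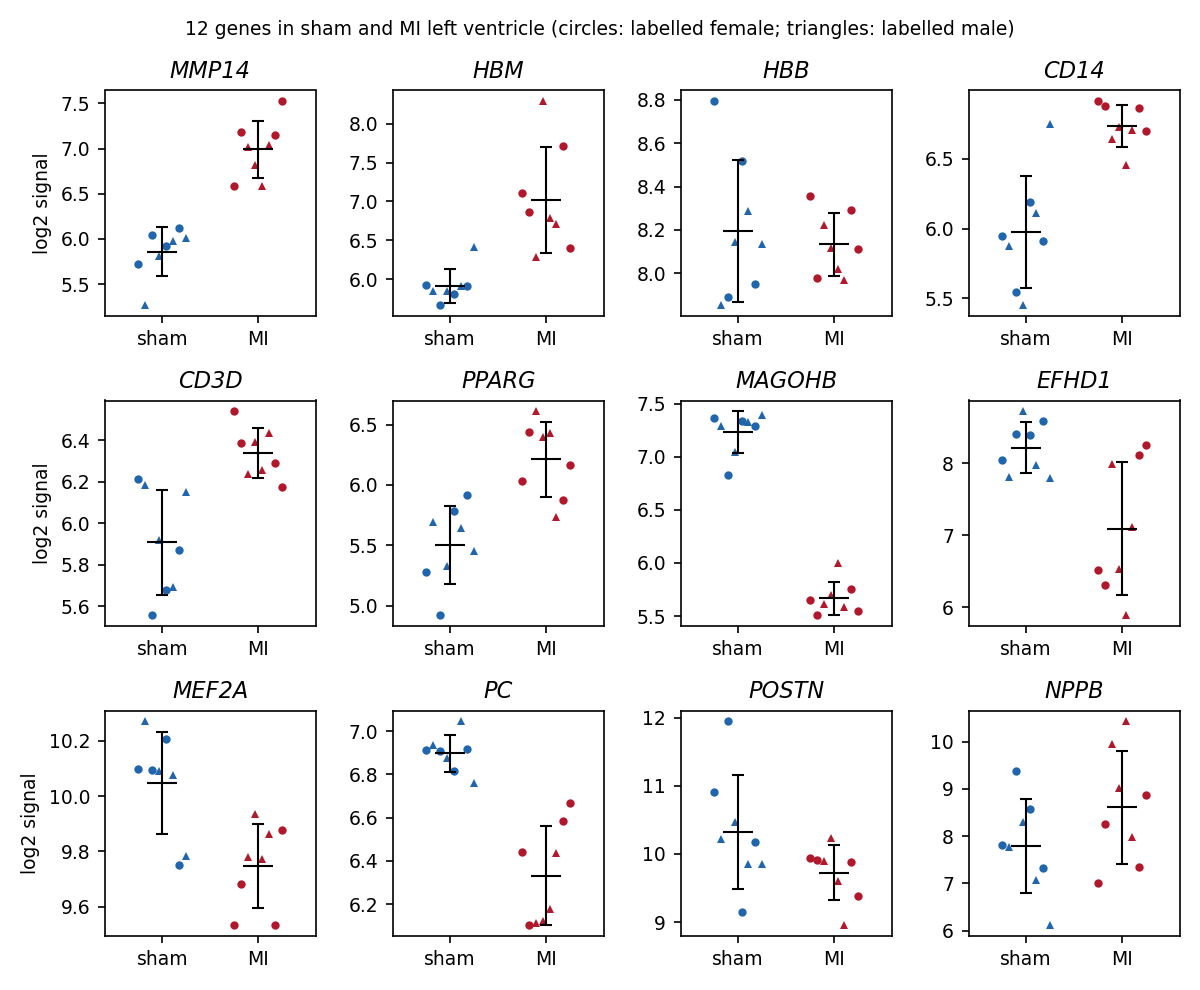
Log2 signal of 12 named genes in each of 8 sham and 8 MI animals (circles labelled female, triangles labelled male; bars, mean and SD). MMP14 rose from 5.86 to 6.99 and MAGOHB fell from 7.24 to 5.67 with no overlap, while POSTN and NPPB, which did not pass, overlap widely.

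Over all probe sets, 2527 of 23999 passed between MI and sham animals, 1294 higher and 1233 lower in MI, and 5673 had an unadjusted p under 0.05. Differences were small: the median size among those passing was 0.35 on the log2 scale, 207 reached 1.5-fold and 10 reached 2-fold. The probe sets passing covered 516 genes, 279 higher and 237 lower. With the spike-in set as a block 3100 passed, 2520 of them among the 2527, in set A alone 2324 passed, and without MI 7 and with the block 2748 passed. Of the 50 named genes that passed, all 50 did so with the block and 37 in set A. The 13 that did not pass there were ADIPOQ, CD247, CD8B, CFP, CSF3, EDNRB, FOSL1, GCLC, GFAP, KDM6A, MYO5B, RETN and RPL23 (adjusted p from 0.0504 to 0.272). Without MI 7 and with the block 40 passed, and ADIPOQ, AHSP, CFP, GFAP, IL7R, KDM6A, RPL23, SERPIND1, TIMP4 and TXLNG did not (0.0505 to 0.103). In set B alone 0 of the 50 passed by limma (2643 of all probe sets had an unadjusted p under 0.05). Newly passing were 6 named genes with the block, 14 in set A and 9 without MI 7 and with the block.

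Among genes of the matrix and its turnover, the passing differences lay in proteases and their inhibitors. Of 21 measured proteases and inhibitors, MMP14, MMP9 and MMP13 rose and TIMP4, an inhibitor of metalloproteinases, fell. MMP13, an interstitial collagenase, rose by 0.43 (adjusted p = 0.000334) and TIMP4 fell by 0.29 (adjusted p = 0.0318), both with signals below background. Of 29 genes of the fibrillar and interstitial matrix 0 passed by limma (1 at an unadjusted p under 0.05), of 5 basement membrane genes 0 (0), and of 18 genes of TGF-beta and BMP signalling 0 (2). TGFB1, the growth factor itself, differed by -0.44 (adjusted p = 0.117) and passed with the spike-in set as a block (-0.36, 0.0232) and in set A (-0.32, 0.0471), in a range of 0.0146 to 0.889 over 30 alternatives. Another probe set of TGFB1 passed in the opposite direction. POSTN, a matrix protein of activated fibroblasts, was 9.73 ± 0.40 in MI and 10.32 ± 0.84 in sham animals (adjusted p = 0.257) and passed without Sham 5 (adjusted p = 0.0461; 0.0461 to 0.601 over 30 alternatives). BGN, the proteoglycan biglycan, differed by -0.32 (adjusted p = 0.442) and COL15A1 by -0.27 (adjusted p = 0.224). The call of TIMP4 ended without any 1 of MI 1, 2 or 4 or Sham 1, 2, 4, 5 or 7 (adjusted p up to 0.0654).

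Markers of infiltrating cells moved in part. Of 13 measured T and NK lymphocyte markers 4 rose: CD3D, a chain of the T cell receptor complex, from 5.91 ± 0.25 to 6.34 ± 0.12 (adjusted p = 0.0116), CD8B by 0.30 (0.0205), CD247 by 0.34 (0.0248) and IL7R by 0.32 (0.0324, below background). CD4 fell by 0.24 (adjusted p = 0.0462, below background); it lies outside the naming rule and was chosen after its values were seen. Of 15 macrophage and monocyte markers 1 rose, CD14, while CD86 differed by 0.39 (adjusted p = 0.182). Of 6 neutrophil markers 1 rose, MMP9, which the protease list also holds and whose sham mean lay below background. Of 3 mast cell markers 1 rose, MS4A2, a chain of the IgE receptor, by 0.69 (adjusted p = 0.0425). Of 29 cytokines and chemokines CSF3 rose by 0.32 (adjusted p = 0.0173) and CCL3L1, a chemokine that draws monocytes, fell by 0.66 (adjusted p = 0.00243). Of 20 interferon response genes 0 passed by limma (0 at an unadjusted p under 0.05), and of 18 antigen presentation genes 0 (0). Of 20 complement and coagulation genes F5, coagulation factor V, rose by 0.53 (adjusted p = 0.00048, below background), while CFP fell by 0.25 (0.0254) and SERPIND1 by 0.28 (0.028).

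Several of these calls ended when 1 animal was left out. CD247 did not pass without MI 4, MI 6 or Sham 3 (adjusted p up to 0.0513), CFP without MI 2, 4, 5 or Sham 6 (up to 0.0543), and SERPIND1 without MI 2, 3, 7 or Sham 7 (up to 0.0616). Over 30 alternatives of all kinds the adjusted p by limma ran up to 0.618, 0.982 and 0.498 in that order. IL7R did not pass without any 1 of MI 1, 2, 3, 4 or 7 or Sham 3, 4, 5 or 8 (up to 0.0689), and MS4A2 without any 1 of MI 1, 2, 3, 5, 6 or 7 or Sham 3, 4, 6, 7 or 8 (up to 0.0856). CD4 passed only without MI 8, Sham 1 or Sham 3 and not without any 1 of the other 13 animals (up to 0.094).

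Among blood and fat cell markers, HBM, a minor alpha-type globin, rose from 5.92 ± 0.22 to 7.02 ± 0.68 (difference 1.10, SE 0.24, adjusted p = 0.00843) and AHSP, the chaperone of alpha globin, by 0.83 (adjusted p = 0.0376), a call that ended without any 1 of MI 1, 2, 4, 5 or 7 or Sham 2 to 7 (up to 0.0727). These were 2 of the 4 measured erythroid markers. ALAS2, the heme enzyme of red cells, differed by 0.59 (adjusted p = 0.22), and HBB, the abundant beta globin, by -0.06 (95% confidence interval -0.32 to 0.20, adjusted p = 0.817). Of 9 adipocyte markers PPARG and ADIPOQ rose and RETN fell, ADIPOQ by 0.44 (adjusted p = 0.0336, below background) and RETN by 0.27 (adjusted p = 0.0414). RETN was not among the 16000 brightest probe sets. ADIPOQ did not pass without any 1 of MI 1, 3, 4, 5 or 7 or Sham 1, 5, 6, 7 or 8 (up to 0.0695), and RETN passed only without Sham 4, Sham 7 or Sham 8 and not without any 1 of the other 13 animals (up to 0.0852).

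Heart muscle genes showed few passing differences. By limma 0 genes passed of 15 cardiac stress and fetal genes (2 at an unadjusted p under 0.05), of 17 sarcomere genes (0), of 15 calcium handling genes (2), of 11 ion channel and gap junction genes (1), of 11 cardiomyocyte markers (0) and of 5 atrial markers (0). NPPB, the B-type natriuretic peptide and a marker of wall stress, was 8.61 ± 1.2 in MI and 7.79 ± 0.995 in sham animals (difference 0.82, SE 0.42, adjusted p = 0.259), and NPPA, the atrial peptide, differed by -0.30 (adjusted p = 0.496). Of 12 cardiac transcription factors 2 fell: NFATC1, a calcineurin-regulated factor, by 0.45 (adjusted p = 0.00356) and MEF2A by 0.30 (adjusted p = 0.0341). NFATC1 was not among the 16000 brightest probe sets, so it was not clear of the dim range. MEF2A passed only without MI 4, MI 8, Sham 7 or Sham 8 and not without any 1 of the other 12 animals (up to 0.0699). Of 20 genes of renin-angiotensin, adrenergic, endothelin and natriuretic signalling 1 rose, EDNRB, the endothelin B receptor, by 0.43 (adjusted p = 0.0144), while another probe set of EDNRB passed in the opposite direction.

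Metabolic and housekeeping genes gave few passing differences. By limma 0 genes passed of 55 genes of oxidative phosphorylation (4 at an unadjusted p under 0.05), of 32 of fatty acid uptake and oxidation (5), of 20 of glycolysis and glucose uptake (1) and of 7 of creatine and phosphotransfer (1). The only passing member among 23 genes of the citric acid cycle and pyruvate was PC, and PDK4, the kinase that shuts pyruvate dehydrogenase, differed by 0.71 (adjusted p = 0.198). SDHA, a subunit of complex II, differed by -0.23 (adjusted p = 0.183). By limma 0 genes passed of 14 hypoxia response genes (1), of 32 heat shock and unfolded protein genes (4) and of 32 ubiquitin-proteasome and autophagy genes (1). Of 28 antioxidant genes 1 rose, GCLC, which makes glutathione, by 0.44 (adjusted p = 0.0186), and 3 of its 4 other probe sets also rose. Of 51 ribosomal protein genes RPL23 passed (0.15, adjusted p = 0.0472), of 22 cell cycle genes MCM3 (0.35, 0.0329, below background) and of 21 immediate early genes FOSL1 (0.28, 0.0435). RPL23 kept its call only without Sham 1 (up to 0.0925), FOSL1 only without MI 1, Sham 2, Sham 6 or Sham 7 (up to 0.083), and MCM3 lost it without any 1 of MI 2 to 6 or Sham 2 to 6 (up to 0.0672). Over 28 to 30 alternatives of all kinds the adjusted p by limma ran up to 0.987 for RPL23, 0.404 for FOSL1 and 0.943 for MCM3.

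Markers of other resident cells gave 0 passing genes by limma among 10 of fibroblasts (0 at an unadjusted p under 0.05), 9 of smooth muscle and myofibroblasts (0), 12 of endothelium (1) and 5 of mesothelium and epicardium (0). VIM, the filament protein of fibroblasts, differed by -0.14 (adjusted p = 0.46), ACTA2, smooth muscle actin, by -0.14 (0.532) and PECAM1, an endothelial adhesion protein, by 0.27 (0.344). Of 5 nerve and Schwann cell markers GFAP passed (0.27, adjusted p = 0.0468), but only with all animals or without MI 3, MI 5, Sham 2 or Sham 4 (up to 0.0919). Of 8 X genes that often escape inactivation TXLNG and KDM6A fell, both by 0.29 (adjusted p = 0.0309 and 0.0392). TXLNG did not pass without any 1 of MI 1 to 4 or Sham 3 to 7 (up to 0.0635), and KDM6A passed only with all animals or without MI 1, MI 4 or Sham 3, not without any 1 of the other 13 animals (up to 0.0806). In set B alone TXLNG differed by 0.25 and KDM6A by 0.04, the other sign. Set B was run without sex and by the labels held 2 MI females, 1 sham female and 2 sham males. Since these 2 genes were higher in females, the set B differences mix group and sex for them. MI 7, with the male pattern at chromosome Y transcripts, is 1 of those MI females. The lists of B lymphocyte markers and of sex-linked genes had 2 measured genes each and were not tested.

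As whole lists, 0 of the 40 moved more than other genes between MI and sham animals by camera (3 at an unadjusted p under 0.05), 0 with an estimated correlation (0) and 0 by the directional test of fry. The mixed test of fry, for change in either direction, passed for 5: proteases and inhibitors (adjusted p = 6.14e-15), complement and coagulation (2.87e-05), adipocyte markers (0.00489), T and NK markers (0.00809) and escape genes (0.0385). The lowest camera value was that of the cell cycle list (median 0.23, adjusted p = 0.116; with an estimated correlation adjusted p = 0.981). It passed without MI 7 (0.000126), Sham 2 (0.0102) or Sham 7 (0.00982) and in set A (0.0193), and not with the set as a block (0.232), in a range of 0.000124 to 0.981 over 31 alternatives. AURKA, a mitotic kinase, differed by 0.48 (adjusted p = 0.0642; 0.00557 without MI 7, and up to 0.853 over 30 alternatives). Counts of passing members were the same when adjusted over the list alone in 35 lists. In the other 5 the adjusted over the list alone counts were 0 for ribosomal proteins, cell cycle and immediate early genes, 1 higher and 1 lower for neutrophil markers, and 3 lower for escape genes. Median, mean and camera's direction differed in sign in 8 lists, all far from passing (adjusted p from 0.869 to 0.931): cardiac stress, oxidative phosphorylation, TGF-beta, complement, hypoxia, adipocyte, atrial and mesothelial.

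Most of the MI differences lay in dim probe sets. Of the 2527, 2152 (85.2%) were below the median mean signal and 375 above it, which is 17.9% and 3.13% of the probe sets there, and 1342 were above background. When the 12000 brightest probe sets were tested alone, 68 passed. Groups without overlap between the 8 MI and 8 sham animals occurred in 711 probe sets, where chance gives 3.73. Of the 23 control probe sets without target RNA, 7 differed after adjustment (5 higher and 2 lower in MI; exact permutation tests, two-sided), and their mean was 3.80 ± 0.03 in MI and 3.73 ± 0.05 in sham animals (n = 8 each, exact p = 0.00684). SRY, the male-determining gene on chromosome Y, was below background and still rose, by 0.39 over both sexes (adjusted p = 0.00218), by 0.31 in females and by 0.48 in males. The MI differences of probe sets whose groups did not overlap in set A had the same direction in set B for 92.8% of those below the median signal and 61.3% of those above it. Over all probe sets the differences of set A and set B had a correlation of 0.521 below the median signal and 4.72e-05 above it.

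**Figure D3:**
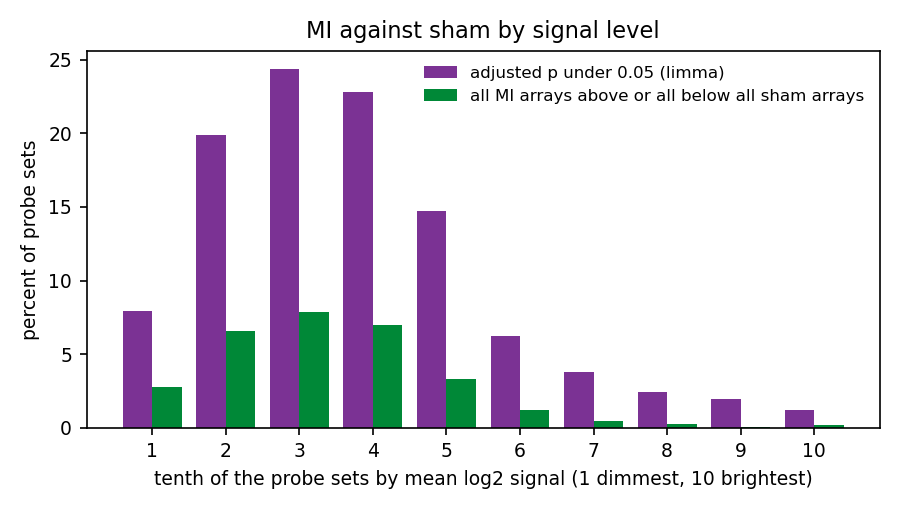
Percent of probe sets that passed between MI and sham animals, and percent whose 8 MI and 8 sham values did not overlap, in 10 groups of 2399 or 2400 probe sets ordered by mean signal. The share passing peaks at 24.4% in the third group from the dim end and is 1.21% in the brightest.

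MMP14, MAGOHB and SSTR1 passed in each sex. SSTR1 was not among the 16000 brightest probe sets, and in sham animals it ran from 4.12 to 4.47, below background (4.99). In females MMP14 rose by 1.16 (adjusted p = 0.00558), MAGOHB fell by 1.59 (5.95e-05), CD14 rose by 0.94 (0.022) and SSTR1 rose by 0.91 (0.000883), with 4 animals in each group. In males MMP14 rose by 1.10 (adjusted p = 0.00716), MAGOHB fell by 1.55 (9.04e-05), PC fell by 0.69 (0.00526) and SSTR1 rose by 0.70 (0.00399). CD14 in males differed by 0.59 (adjusted p = 0.13) and PC in females by -0.44 (0.0549), and the interaction had an adjusted p of 0.815 and 0.796. In females 685 probe sets passed (379 higher, 306 lower; 3889 at an unadjusted p under 0.05) and in males 816 (422 higher, 394 lower; 4571). Both sexes shared 360 of them, all in the same direction, where 23.3 shared and 11.7 with the same direction would be expected if the calls were independent. They are not fully so, since both comparisons use the same estimate of the spread for each probe set. Over all probe sets the differences in females and in males had a correlation of 0.29. With the spike-in set as a block 891 and 645 passed, and in set A alone 201 and 323, with 2 MI females, 3 sham females, 4 MI males and 2 sham males. The female count was 396 without MI 7, 382 without Sham 1, 376 without Sham 3 and 421 without Sham 5. The male count was 435 without MI 3, 466 without MI 4, 426 without MI 5, 511 without Sham 4, 415 without Sham 6 and 515 without Sham 8.

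Whether the response to MI differed between females and males was tested by the interaction, and 0 probe sets passed by limma (1363 at an unadjusted p under 0.05; lowest adjusted p 0.794). The genes with the lowest p, none of which passed, were LIMA1, an actin-binding protein (-0.27 in females and 0.39 in males, unadjusted p = 0.000534), NQO1, a quinone reductase (-0.17 and 0.53, 0.000641), GRIN1 and TRAF3IP2. NPPB differed by -0.40 in females and 2.04 in males (interaction -2.44, unadjusted p = 0.011, adjusted p = 0.794). By camera 5 lists passed, each with an adjusted p = 0.971 with an estimated correlation, and 0 genes of any list passed singly by limma (52 of 702 list memberships at an unadjusted p under 0.05). The MI minus sham difference of the fibrillar matrix list was lower in females than in males (median interaction -0.39 over 29 genes, adjusted p = 0.000131; 7.93e-05 with the block), as were those of the interferon list (-0.36 over 20 genes, 0.000982; block 0.00303), the heat shock list (-0.07 over 32 genes, 0.0292; block 0.0129) and the cell cycle list (-0.24 over 22 genes, 0.032; block 0.122). That of the neutrophil list was higher in females (0.34 over 6 genes, of which 1 was above background, 0.0182; block 0.0169). Over 27 to 29 alternatives the adjusted p ran from 9.83e-10, 6.28e-07, 0.0062, 2.02e-07 and 0.00146 in the order given up to 0.971 for each. Adjusted over the list alone the counts were 0 for these lists and 1 lower for antioxidant genes, NQO1.

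Tested on the list means of the animals, 0 of the 40 lists passed the interaction after adjustment (exact permutation, 3 at an unadjusted p under 0.05). The test dealt the sex labels anew within each group and so took the sexes as equal in both groups. A sex difference common to both groups widens the spread of the deals. A list that did not pass may therefore still hold an interaction. The mean of the matrix list above that of all genes was 1.81 ± 0.13 in MI and 2.14 ± 0.51 in sham females, 1.82 ± 0.24 in MI and 1.67 ± 0.16 in sham males (n = 4 each), an interaction of -0.49 (exact permutation test over 4900 deals of the sexes, two-sided, p = 0.131, adjusted over 40 lists 0.952). Without MI 7 the MI female mean was 1.85 ± 0.12 (n = 3) and the interaction -0.44 (exact p = 0.198). The interferon list gave 0.50 ± 0.41, 0.70 ± 0.31, 1.07 ± 0.40 and 0.81 ± 0.31 in that order, an interaction of -0.46 (exact p = 0.266, adjusted 0.952), and without MI 7 the first was 0.54 ± 0.48 and the interaction -0.41 (exact p = 0.353). Exact p was 0.0049 for the neutrophil list and 0.0098 for the heat shock list (both adjusted 0.196), and 0.392 for the cell cycle list (adjusted 0.955).

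By camera the median of the matrix list was -0.23 without Sham 3 (adjusted p = 0.0231). That of the interferon list was -0.61 without MI 1 (7.44e-06), -0.23 without MI 5 (0.0938, no longer passing), -0.20 without MI 8 (0.00557) and -0.23 without Sham 3 (0.0269). The neutrophil call ended without MI 1 (0.0686), MI 2 (0.0689) or Sham 7 (0.119), and its median was 0.22 without Sham 6. The heat shock call ended without MI 2, 4, 5 or 8 or Sham 2, 6 or 7 (adjusted p from 0.0534 to 0.119), with medians of -0.04 without MI 2 and -0.02 without MI 8. The cell cycle call ended without MI 1, 4, 5 or 7 or Sham 3, 6, 7 or 8 (up to 0.684, Sham 7), its median ran from -0.07 without MI 7 to -0.45 without Sham 5, and moved by over 1.5 times also without MI 2, MI 5, Sham 2, Sham 6 and Sham 7. In set A alone that list had the other sign (0.18).

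**Figure D4:**
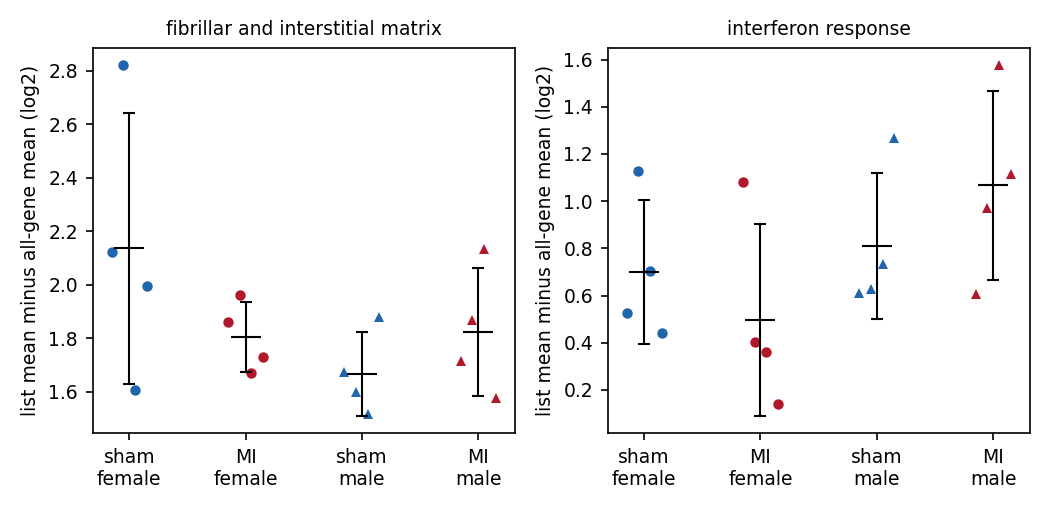
Mean log2 signal of the 29 fibrillar matrix genes and the 20 interferon response genes minus the mean of all genes, per animal, in sham and MI females and males (n = 4 each; bars, mean and SD). The groups overlap: matrix means are 2.14 in sham and 1.81 in MI females, and 1.67 and 1.82 in males.

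Female and male animals were compared to describe sex differences and to check the labels. EIF1AY, a translation factor gene on chromosome Y (Entrez 100625415, 9687350 to 9704489), was 5.55 lower in animals labelled female (SE 0.70, adjusted p = 0.00237), and LOC396706 on chromosome Y was 0.96 lower (0.00241). KDM6A, a histone demethylase gene on chromosome X (Entrez 100154376, 39953764 to 40154197), was 0.76 higher in females (SE 0.09, adjusted p = 0.00163) and TXLNG, also on X, 0.52 higher (0.0149). TXLNG did not pass without MI 3, MI 4, Sham 2 or Sham 5 (up to 0.0544). These were the 4 genes among 14 probe sets that passed, 7 higher and 7 lower in females (746 at an unadjusted p under 0.05), and 15 passed with the spike-in set as a block. Over 26 to 28 alternatives the adjusted p by limma ran from 2.07e-15 to 0.158 for EIF1AY and from 0.000807 to 0.372 for LOC396706. It ran from 0.000383 to 0.743 for KDM6A and from 0.00549 to 0.995 for TXLNG. The lowest value for EIF1AY came with 1 array left out. MI 7, counted as female here, had 9.51 at EIF1AY, against 3.27 ± 0.16 in the 7 other labelled females. MI 7 thereby widened the spread and the SE at that gene.

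In the library labelled MI female 7 EIF1AY was 9.51, against 9.60 ± 0.18 in the 8 labelled males and 3.27 ± 0.16 in the 7 other labelled females. That library lay nearer the males at 12 of the 14 probe sets, including all 9 that differed by over 3 on the log2 scale, and nearer the females at TXLNG and KDM6A. In sham animals alone, where this library takes no part in the difference, 13 probe sets passed, among them EIF1AY (-6.26), LOC396706 (-1.25) and KDM6A (0.83). That count was 6 without MI 3, MI 4, MI 5 or MI 6, which alter only the estimate of the spread, and 0 without any 1 of Sham 1 to 8 by limma, and 9 with the spike-in set as a block.

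With MI 7 counted as female, as labelled, 12 of the 40 lists differed between the sexes by camera (16 at an unadjusted p under 0.05). Without MI 7, 15 passed, and 15 also passed without it and with the spike-in set as a block. Of the 12, 1 held with an estimated correlation: the X genes that often escape inactivation, higher in females (median 0.18, adjusted p = 3.6e-06, and 0.00723 with an estimated correlation). The block gave 6.33e-06 for it, and its adjusted p stayed at or under 0.00723 over 29 alternatives. In it 2 of 8 genes, KDM6A and TXLNG, passed over all genes, and 4 higher and 1 lower adjusted over the list alone.

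The interferon list was lower in females (median -0.32, adjusted p = 3.69e-08; block 2.19e-07; median -0.21 without MI 5) and the fibrillar matrix list higher (0.18, 1.63e-07; block 1.34e-08; 0.07 without Sham 3), each with an adjusted p = 0.411 with an estimated correlation (3.52e-12 to 0.623 and 2.4e-13 to 0.411 over 29 alternatives). The complement list was also higher in females (0.11, 0.00152; block 0.00141; adjusted p = 0.19 with an estimated correlation, 5.47e-05 to 0.925 over 29 alternatives). In these 3 lists 0 genes passed by limma over all genes or adjusted over the list alone (6, 0 and 2 at an unadjusted p under 0.05). Lower in females by camera were also antigen presentation (-0.19, adjusted p = 0.00288), oxidative phosphorylation (-0.05, 0.00864), T and NK markers (-0.15, 0.00892) and the ubiquitin-proteasome list (-0.07, 0.018). Higher were fibroblast markers (0.14, 0.0101), smooth muscle markers (0.11, 0.018), TGF-beta signalling (0.06, 0.018) and proteases (0.05, 0.0263). With an estimated correlation these 8 had adjusted p from 0.28 to 0.679, and 0 of their genes passed by limma (5 at an unadjusted p under 0.05). With the block 7 of them passed and the smooth muscle list did not (0.0707; 0.00238 to 0.71 over 29 alternatives).

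Each of these 8 calls ended when 1 of several animals was left out. Antigen presentation did not pass without MI 5 or Sham 8 (adjusted p up to 0.0661), oxidative phosphorylation without MI 6, Sham 6 or Sham 7 (0.118), T and NK markers without MI 6, MI 7, Sham 2 or Sham 8 (0.0805), and the ubiquitin-proteasome list without MI 6, MI 8 or Sham 7 (0.118). Fibroblast markers did not pass without MI 1, MI 2, MI 6 or Sham 3 (0.1), smooth muscle markers without MI 6, MI 8, Sham 6 or Sham 7 (0.199), TGF-beta signalling without MI 1, MI 3, MI 6, Sham 6 or Sham 7 (0.129) and proteases without MI 1, MI 2, MI 6, Sham 3 or Sham 6 (0.177). Among the omissions that ended a call, the median came to 0.04 for fibroblast markers and 0.02 for proteases without Sham 3. Without Sham 7 it came to 0.01 for smooth muscle markers, 0.01 for TGF-beta signalling and -0.03 for oxidative phosphorylation, and without MI 7 to -0.08 for T and NK markers. Medians also moved by over 1.5 times without MI 1 for T and NK markers (-0.24), without Sham 4 for TGF-beta signalling (0.03), and without MI 7 (0.11), Sham 2 (0.08) or Sham 8 (0.03) for proteases. Over 29 alternatives the highest adjusted p of these lists was from 0.561 for T and NK markers to 0.925 for fibroblast markers. Over both groups the sign of median, mean and camera's direction differed in 6 lists, none of which passed.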

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

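Of the tests in this part, those on the control probe sets and the spike-in set behind the dim probe sets, all 3 on the library labelled MI female 7, and those on the spike-in set and that library behind the matrix list, and the splits of females with the spike-in set as a block, were chosen after the result was seen, and the tests on other probe sets of a gene, on list means and on the other splits before.

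A value far from the rest of its group was looked for in 200 groups of animals at the genes printed here, and 23 held one, where chance gives about 1 in 20 groups. In MI animals MYO5B was 6.77 in MI 3 (others 5.41 to 5.68), IYD 6.85 in MI 6 (6.12 to 6.46), and BGN 10.01 in MI 5 (8.93 to 9.28). MI 8 lay apart at MMP13 (3.81, others 4.03 to 4.17), IL7R (4.47, 4.89 to 5.10), MS4A2 (6.25, 7.15 to 7.79) and CD4 (4.81, 4.22 to 4.47). In sham animals MMP14 was 5.26 in Sham 2 (5.72 to 6.12), FPGT 7.82 in Sham 1 (6.44 to 7.09), BGN 11.15 in Sham 3 (9.03 to 9.85), CPT1A 7.60 in Sham 6 (8.27 to 8.73) and GCLC 4.84 in Sham 7 (5.37 to 5.57). Sham 4 lay apart at SSTR1 (4.47, 4.12 to 4.27), ITPR1 (4.93, 5.16 to 5.31) and NR4A3 (10.53, 7.19 to 8.73), and Sham 8 at HBM (6.42, 5.66 to 5.92), MMP13 (3.44, 3.59 to 3.70) and ALAS2 (7.56, 6.58 to 7.03). MI 7 lay apart from the other MI animals at AURKA (5.13, 6.04 to 6.27), MAD2L1 (7.44, 8.17 to 8.76) and S100A8 (4.35, 3.98 to 4.09), and from the other labelled females at EIF1AY (9.51, 3.00 to 3.51) and LOC396706 (4.23, 3.53 to 3.86). By animal the counts were 5 for MI 7, 4 for MI 8, 3 for Sham 4, 3 for Sham 8 and 1 for each of 8 others.

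The library labelled MI female 7 carried the male pattern at chromosome Y transcripts. A swap with a library labelled male of this series would leave a partner among the males, and 0 of the 8 lay nearer the females at EIF1AY. A mixture of a female and a male sample would raise the female-high probe sets, and in this library the largest excess over the male mean among the 5 of them was 0.441, where females and males differed by at least 4.21. A wrong sex label or a sample from outside the series stays open, with 9 of 9 probe sets over 3 apart nearer the males. No biological explanation was tested.

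MI and sham arrays differed mostly in dim probe sets, and the same was seen in data outside the main comparisons, the control probe sets without target RNA. After adjustment 7 of these 23 differed between MI and sham (exact permutation tests, two-sided), by 0.36, 0.34, 0.39, 0.13, -0.26, 0.30 and -0.27, so a difference between the arrays of the groups that acts without any target RNA stays open as a candidate source. The spike-in set as the whole source is argued against by the 3100 probe sets that passed with it as a block. The direction of other probe sets of the same gene gave no sign of changes in the RNA of the genes named. In the dimmer part of the probe sets 55.8% of these went in the same direction (95% confidence interval 51.4 to 60.2, n = 480). In the brighter part 60.4% did (52.5 to 67.8, n = 154). For probe sets that did not pass the shares were 55.1% and 59.4%, inside those intervals. Of the other probe sets of their genes, 111 and 158 themselves passed in the same direction. This reference therefore also holds genes with a passing probe set. The intervals take probe sets as independent, although the 480 came from 290 genes and the 154 from 103, on the same arrays. This does not exclude changes in the RNA, since it was not tested whether the other probe sets detect the same transcripts. The labels give no order of processing by which a shared day of MI arrays could be weighed, and infarction itself stays open as a source.

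For 5 lists the MI minus sham difference differed between females and males by camera: fibrillar matrix (-0.39), interferon (-0.36), heat shock (-0.074), cell cycle (-0.24) and neutrophil markers (0.34). With an estimated correlation in place of the preset one 0 of the 40 lists passed by camera (1 at an unadjusted p under 0.05), and these 5 had an adjusted p of 0.971. For camera's call of the matrix list, the library labelled MI female 7 and a spike-in set effect equal in all groups are argued against as whole causes. By the labels set B held 0 MI males, so the block cannot separate a set effect that differs by group and sex from the interaction. The adjusted p of that call was 7.93e-05 with the set as a block and 0.000294 without that library (9.83e-10 to 0.971 over 29 alternatives), with a median of -0.23 without Sham 3 (adjusted p = 0.0231). The call rests on the preset correlation between genes, so these values do not show a difference between animals. Matrix genes that vary together from animal to animal stay open as a candidate explanation, since the list means of the animals gave an exact p of 0.131 (two-sided, n = 4 per group and sex). That permutation test took the sexes as equal within each group, so it does not decide the question. A biological difference between the sexes also stays open and was not separated from genes that vary together.

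Other splits of the same arrays were counted, the real one included. Only the real split gave as many passing probe sets for MI against sham (1 of 100 drawn; real 2527, highest other 1) and for males (1 of 35; 816 and 0). The same held for females against males (1 of 100; 14 and 2) and for the same in sham animals (1 of 35; 13 and 1). A random grouping is unlikely there but not excluded, since the number of splits limits how small the share can be. A difference between arrays that runs along with the groups would give the same outcome. For the interaction the real count was 0 by limma (1363 at an unadjusted p under 0.05) and the highest other 1, and since any split gives at least 0 (100 of 100 drawn), the splits say nothing about chance there. For MI against sham in females 2 of 35 gave as many (685 and 944), so a random grouping was not made unlikely. The split with 944 put the 3 set B arrays labelled female in the same group and so followed the spike-in set. With the set as a block 1 of 35 splits gave as many (891 and 2).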

How the results depend on the processing

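Of the alternatives in this part, the spike-in set as a block, sets A and B alone, the block without MI 7, the probe sets above background and the brighter 12000 were chosen after the data were seen.

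The count of probe sets passing between MI and sham animals (2527) stayed within 1.5 times under quantile normalization (2540), median centring (2536), an offset of 32 (2234), trend and robust estimation (2669), array weights (3245), group without sex (2727), the animal number (2395), the spike-in block (3100) and set A (2324). The deposited arrays already shared median and minimum, so quantile normalization and median centring could change little and hardly test the normalization. The interaction gave 0 by limma under each alternative run on it (1363 at an unadjusted p under 0.05 in the first place). For the named genes between MI and sham, 4749 values kept direction and side of the threshold, 297 no longer passed, and 90 passed newly in the same direction. The sign was the other one in 68, of which 65 passed neither before nor after and 39 were in set B alone. For lists, by camera's direction, 1126 values were kept between MI and sham, 7 passed newly in the same direction, 102 took the other direction without passing on either side and 3 with a pass on 1 side. These numbers were 1005, 6, 110 and 4 for the interaction, with 33 no longer passing, and 955, 31, 107 and 3 for the sexes, with 62. Of 50 named genes that passed, 33 did so whichever 1 array was left out and 17 did not. Set B alone was run without sex, since it holds 0 MI arrays labelled male.

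Requiring at least 1.5-fold left 207 probe sets between MI and sham, 175 in females and 252 in males, and an adjusted p under 0.01 left 1123, 139 and 228, and 0 by limma for the sexes in sham (829 at an unadjusted p under 0.05), both by construction stricter. Keeping the 16000 brightest probe sets gave 654, 90 and 131, keeping those above background 993, 200 and 265, and keeping the 12000 brightest 68, 7 and 5, with 7 for the sexes and 6 for the sexes in sham. Signal over background limits these results, since 1185 of the 2527 lay at or below the highest control without target RNA. The 5 in males held MAGOHB, SNRPG and 3 without a symbol, named after their values were seen. Under an offset of 32 the count for the sexes in sham was 0 by limma (882 at an unadjusted p under 0.05), under array weights that in males was 1440, and the cause was not tested for either. In set A alone, with 11 arrays, 201 passed in females and 323 in males, and in set B, with 5 arrays, 1 passed between MI and sham, without a symbol (2643 at an unadjusted p under 0.05).

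The 1 list passing between MI and sham under array weights, with the mean over the probe sets of a gene, in set A alone and in the block without MI 7 was the cell cycle list each time. The 3 in set B alone were interferon (-0.52), antigen presentation (-0.22) and macrophage markers (-0.31), each turned from a median above 0 that did not pass (0.05, 0.03 and 0.05). Among results that passed on either side, directions also turned in set B for EFHD1 (0.065), KDM6A (0.041) and TXLNG (0.25), and in set A for the interaction of the cell cycle list (0.18, no longer passing) and of cardiac transcription factors (-0.14, newly passing). KDM6A and TXLNG were higher in females. By the labels set B held 2 MI females, 1 sham female and 2 sham males, and it was run without sex. Its differences for these 2 genes therefore mix group and sex. MI 7, which carried the male pattern at chromosome Y transcripts, is 1 of those MI females. Between the sexes the cell cycle list passed with a turned direction in the block without MI 7 (0.049). The cause was not tested for any of these. With the animal number as a block 3 probe sets passed in females (MAGOHB and 2 without a symbol), 1 in males (MAGOHB), 0 by limma for the sexes (1237 at an unadjusted p under 0.05) and 0 for the sexes in sham (947), and the oxidative phosphorylation list turned to 0.012 between the sexes, no longer passing, while the interaction turned and passed for endothelial markers (-0.47) and T and NK markers (-0.31), and the cause was not tested. That block takes up degrees of freedom, the labels give no meaning to a shared number, and animals were not taken as paired, since not every pair deviated together: correlations of an MI animal with the sham animal of its number ran from -0.216 to 0.504, 5 of 8 over 0.1, and 3 of 8 were the best of that animal. A pairing of some of the animals was not excluded.

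Leaving out each animal in turn gave 2045 to 2537 probe sets between MI and sham, 376 to 710 in females (376 without Sham 3), 415 to 950 in males (415 without Sham 6), 0 to 0 for the interaction by limma, 13 to 18 for the sexes and 0 to 16 for the sexes in sham (0 without any 1 of Sham 1 to 8, 16 without MI 7), and 0 to 1 lists between MI and sham (1 without MI 7, Sham 2 or Sham 7). The median of the cell cycle list between the sexes ran from -0.12 without MI 2 to 0.057 without MI 7, when it passed (adjusted p = 0.0458; 0.0454 to 0.995 over 29 alternatives).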

Other observations

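The test of NPPB against the matrix list was chosen before its result was seen, and the genes in the next paragraph by the rule for naming genes, so no test in this part was chosen after the result was seen.

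Several genes with sizeable differences between MI and sham animals did not pass. NR4A3, a nuclear receptor of the immediate early response, was 7.17 ± 1.37 in MI and 8.39 ± 1.02 in sham animals (difference -1.23, adjusted p = 0.0923, lower than the sham mean in 6 of 8 MI animals), with -2.26 in females and -0.19 in males (interaction adjusted p = 0.794). KCNJ5, a potassium channel subunit, differed by -0.79 (adjusted p = 0.166), and CCL4, a chemokine, by -0.74 (0.121), with all 8 MI animals below the sham mean of CCL4. KIT, the stem cell factor receptor of mast cells, differed by 0.55 (0.328) and MAD2L1, a mitotic checkpoint protein, by 0.47 (0.105). Without MI 7 MAD2L1 passed (adjusted p = 0.015; 0.0119 to 0.887 over 30 alternatives).

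NPPB differed widely between MI animals (SD 1.2, n = 8), and the hypothesis was that matrix transcripts follow it as a measure of wall stress. The mean of the matrix list and NPPB had a Pearson correlation of 0.436 in the 8 MI animals (exact permutation p = 0.28, two-sided; Spearman 0.452, exact p = 0.267) and of 0.205 without the 2 animals farthest from the rest. The relation was not shown, and 8 animals are too few to exclude one of this size.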
